A study of Mus musculus with 8 samples.

How the data were processed

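Gene expression was measured on 8 Agilent arrays of design 074809, all on 1 slide, each hybridised with Cy3-labelled material from 1 sample of male mouse brain, kidney or liver. Labelling started from 50 ng of total RNA, per the labels' protocols. Group, tissue and dose came from the labels, which name 1 sample per group. The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 12.0.3.1, per the submitters' processing notes. The processed intensity was background-subtracted and detrended but not scaled between arrays, per the file headers. Other columns used are 0 or 1 flags of the scanner software for spots well above background, saturated, not uniform or outlying, per the file headers. The deposited value table holds intensity too. Set against the scanner files it equals each array's processed intensity divided by that array's 75th percentile over all spots, so its scale is linear and its direction that of the scanner signal. Its column medians were 0.112, 0.113 and 0.114 for brain, 0.0940, 0.0905 and 0.0936 for kidney (control, low and high dose) and 0.0915 and 0.0918 for liver (control and high dose).

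Control spots and spots marked as not uniform or as outliers were left out, and spots of 1 probe were averaged as log2 values. From each array the 75th percentile of its log2 processed signal over non-control spots was subtracted. The array design has 56605 non-control probes. Gene names were updated through a RefSeq gene table (assembly GRCm38.p6, used for names only), which matched 32989 probes by accession and changed 1534 names, while 23616 probes kept the name in the files. The plan had been to keep all names as in the files. Probe positions are those of the array files, in mm9, with no conversion to another build. A gene was reported by its probe with the highest mean level over the 8 arrays, and for a gene past the size rule the values of its other measured probes are given where any falls short of it.

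The choice of comparisons, the size rule, the gene lists, the rule for named genes and the alternatives were made before the data were examined. A gene counted as higher or lower when its log2 difference was at least 1 in size, when its reported probe was well above background and not saturated on both arrays, and when the difference was more than 3 times its array error. The array error is the root of the summed squared relative errors of both spots as the scanner software reports them, on the log2 scale. For a gene well above background on 1 array only, a lower bound of the fold was computed from the bright level and the higher of the dim probe's own value and the lowest signal well above background on the dim array.

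Named genes were the 8 largest in each direction per comparison of the high dose with control, 5 for the low dose and 3 for high against low dose, with the 4 or 2 largest transporters and the 2 largest bounds in each direction. Clone and model names were counted but not named. Some results that the rule would name are not reported here. Any member of a metal list and up to 4 members of another list were named too. The 80 lists cover transporters, metal handling, stress responses, metabolism, immunity and cell types. For each list with at least 4 detected members, the median difference was ranked among 10000 random lists of the same size matched on mean level in 20 bins, and a list stood apart below percentile 2.5 or above 97.5. This describes the arrays and is not a test of the conditions.

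Effects shared by the tissues were fitted with limma 3.58.1 in R 4.3.3 (tissue and dose as factors, empirical Bayes with an intensity trend, 3 residual degrees of freedom) on genes well above background on all 8 arrays, with Benjamini-Hochberg adjustment. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest. The methods were tested on simulated data. For the high dose in brain, the size rule found 100 of 100 genes changed by 1.5 and 100 of 100 changed by 2. It called 3 unchanged genes among 22796. Of unchanged lists 6.9% stood apart, and of lists shifted by 1 SD 97.0%. The noise here was drawn from the array error alone, for each gene separately, without variation between animals or tissue pieces. The size rule uses that same error, so these values give no false-call rate for the real comparisons. For the high-dose effect across tissues, limma found 80%, 98%, 100% and 100% of genes changed by 0.5, 1, 2 and 3. It made 12 false calls among 17448 genes. This simulation drew noise from variances already moderated across genes and gave a changed gene the same effect in every tissue. Recovery can be lower where variances or effects differ more, so the absence of calls in the data does not exclude shared effects of these sizes.

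The share of spots well above background was 64.0%, 65.8% and 67.1% in brain, 61.0%, 58.5% and 60.6% in kidney, and 53.4% and 54.0% in liver. Spots of probes repeated 10 times on an array varied by a median of 2.71% to 3.44%, and at most 1 spot per array was saturated. The negative-control measure of the scanner software was outside its stated range on all 8 arrays. All arrays share 1 slide, so no slide or scan batch could be told apart. The number of arrays, 1 per group, limits the precision. Alternatives tried were normexp background correction with quantile normalization, other scalings, the deposited value table, looser and stricter filters on dim probes, the mean of a gene's probes, fold limits of 1.5 and 3, no requirement on the array error, random lists without matching, and for limma other filters, no intensity trend, dose as a number and leaving out a tissue or the low-dose arrays. A count without marker genes was added after seeing the data.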

Results

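The series asked how lead exposure through drinking water alters gene expression in mouse tissues, with transporter genes named as its subject. Male mice drank distilled water or lead acetate at 100 mg/L (low dose) or 1000 mg/L (high dose) for 3 weeks. Total RNA from pieces of brain, kidney and liver was labelled with the dye Cy3 and hybridised to Agilent arrays of 1 design. There were 8 arrays and 8 groups. Brain and kidney had a control, a low-dose and a high-dose array each, and liver had a control and a high-dose array. The 8 samples include no low-dose liver array. Each group had 1 array, so no difference between groups has a replicate check and no p-value is given for a single tissue.

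Between 53.4% and 67.1% of spots were well above background. The 75th percentile of the scanner signal was 919 to 954 on brain arrays, 729 to 782 on kidney arrays and 427 to 435 on liver arrays. All levels below are log2 values relative to that percentile, and all differences are log2 differences of such levels. Between 51.4% and 62.1% of the 37324 gene names were measured on both arrays of a comparison. A gene was called higher or lower when it differed by at least 1, that is 2-fold, and by more than 3 times its array error. The array error was 0.21 for the median gene, most of it a fixed relative error of the scanner software. For probes repeated within an array, the difference between arrays varied from spot to spot with a root mean square SD of 0.04 to 0.07. That spread leaves out any difference that all spots of a probe share. Over the measured genes of a comparison the SD of the differences was 0.24 to 0.34.

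The tissue labels were checked first on fixed sets of tissue-specific genes. The median level of brain genes was 5.39 to 5.42 on the brain arrays and -2.45 or lower elsewhere. Kidney genes stood at 4.79 to 4.88 on the kidney arrays and liver genes at 9.56 and 9.60 on the liver arrays. On the kidney arrays the liver genes had a median level of -0.44 in the control, -0.34 at the low dose and 0.74 at the high dose. Arrays of the same tissue correlated across probes at 0.995 to 0.997, and arrays of different tissues at 0.727 to 0.877.

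Transporters, the subject named by the series, were counted in 4 families with 520 members on the array. In the kidney at the high dose, 11 transporters were higher and 5 lower among 422 measured, or 3.79% against 1.67% of all genes, a share at percentile 99.99 of random gene sets. Among 37 measured ABC transporters, which pump substrates across membranes with ATP, 5 were higher and 0 lower. They were the P-glycoprotein genes Abcb1b (1.70, array error 0.21) and Abcb1a (1.10), the phospholipid exporter Abcb4 (1.39), and the multidrug resistance-associated pumps Abcc3 (1.53) and Abcc4 (2.83-fold). Of 319 measured SLC transporters, 4 were higher and 5 lower. The higher ones were the sulfate carrier Slc13a4 (1.48), Slc4a11 (1.42), the organic anion carrier Slco4a1 (1.38, other probes -0.08 and 0.05) and the zinc importer Slc39a4 (1.34). The lower ones included the organic anion carriers Slc22a7 (-1.86), Slc22a26 (-1.47) and Slc22a19 (-1.35), with Slc26a7 (-1.09) and Slc29a4 (-1.04). The remaining higher members were Atp1a4 (2.05), a sodium pump subunit of sperm, and the water channel Aqp8 (1.02). Genes of sperm formation were higher on this array too, and the share of transporters was not recomputed without Atp1a4. The probe of Abcb1b lies on chromosome 5 from 8865925 to 8865984 and that of Slc22a7 on chromosome 17 from 46569272 to 46569331 (mm9 coordinates of the array files). The naming rule took the 4 largest transporters in each direction, and the others named here were chosen after their values were seen.

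Fewer transporters passed the size rule in the other comparisons with a control. In the kidney at the low dose 2 of 419 were higher and 2 lower, in the brain 2 and 0 of 407 at the low dose and 1 and 2 of 409 at the high dose, and in the liver 1 and 0 of 361. The share among transporters lay at percentiles 96.4, 34.9, 83.5 and 14.98 of random gene sets. The liver gene was Slc41a3, a magnesium carrier (1.28). In the liver the list medians of SLC (0.02) and ABC transporters (0.09) lay above the upper limit of random lists, with 268 and 39 members measured on both arrays and no further member past the rule. The SLC call ended without a filter on dim probes, where the median was -0.04, and with the mean of probes. Between high and low dose, 9 transporters were higher and 3 lower of 421 in the kidney, and 4 and 6 of 412 in the brain, at percentiles 99.99 and 99.5. The lower ones in brain include Aqp1 and Slc4a5, which are choroid plexus markers, and Slc10a4 and Slc35d3, which were higher at the low dose along with striatum markers. The higher ones in brain were Slc9b1 (2.29), Aqp8 (1.29), the sperm subunit Atp1a4 (1.24) and Slc23a3 (1.01, second probe 0.10). Genes of sperm formation were higher on the high-dose brain and kidney arrays, and these shares were not recomputed without Atp1a4. Whether the kidney differed from the other tissues was not tested.

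Metallothioneins, small cysteine-rich proteins that bind zinc, copper and cadmium, were higher in liver (Mt1 3.11, Mt2 2.99; array error 0.20 for both) and in kidney (Mt1 1.27, second probe 0.49; Mt2 1.20). In the brain at the high dose Mt1 differed by 0.25 and Mt2 by 0.17, and in the kidney at the low dose by 0.28 and 0.24, short of the rule. The Mt1 probe lies on chromosome 8 from 96704165 to 96704224, and a second, measured Mt1 probe gave 0.48 in the liver. Of the heme genes, Hmox1, which breaks heme down, was higher in the kidney at the high dose (1.18), while the lead-sensitive enzyme gene Alad differed by -0.10 there, -0.16 in the brain and 0.03 in the liver. The heme list had 1 of 13 members past the rule in the high-dose kidney, with a median of 0.14, and the iron list 2 of 16, with a median of 0.12; both medians lay above the upper limit of matched random lists. The iron genes past the rule were the plasma copper oxidase Cp (1.95, other probes -0.12 to 1.15) and Tfr2, a transferrin receptor (1.39); genes typical of liver had a median difference of 0.85 on the same array. In the liver Hjv, a regulator of the iron hormone hepcidin, was lower (-1.01). Zinc and manganese carriers and copper genes had medians of -0.06 and -0.01 in the high-dose kidney, inside the range of random lists. In the low-dose kidney the zinc importer Slc39a4 was higher (2.27) and its relative Slc39a2 lower (-1.27).

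In the brain at the low dose, markers of the striatum, the dopamine-receiving part of the forebrain, were higher and markers of the hippocampus lower than in the control. All 11 measured striatum markers passed the rule, with a median of 1.56. They included the G-protein regulator Rgs9 (1.92), Syndig1l (1.90), the adenosine receptor gene Adora2a (1.76) and the dopamine receptor gene Drd1 (1.67). Among 8 hippocampus markers 4 were lower, with a list median of -1.34: Spink8 (-2.52), Lct (-2.08), Fibcd1 (-1.84) and Dsp (-1.69). Pituitary hormone genes were near or below background on the exposed array: Prl, which encodes prolactin, was at least 12.8-fold lower and Gh, growth hormone, at least 5.80-fold lower. Such a bound sets the bright level against the higher of the dim probe's own value and the lowest signal well above background on its array. The pituitary list had 5 detected members, only 1 of them on both arrays, and a median of -3.18, or -1.01 with dim members at their bound. The member on both arrays, Lhb, differed by 0.14, and the list did not stand apart without a filter on dim probes (median -0.19) or with the mean of probes (0.14).

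The largest single differences in the low-dose brain included Sh3rf2 (2.61, array error 0.35), the retinoid receptor Rxrg (2.24, array error 0.20), Slc10a4, a carrier-like protein of synaptic vesicles (2.24), the protease inhibitor Serpina9 (2.16) and the tryptophan-degrading enzyme Ido1 (2.11). A second transporter, Slc35d3, a nucleotide sugar carrier, was higher by 1.78. Lower genes were Spink8 and Lct, given with the hippocampus markers, Stac (-2.03), Lefty1 (-2.02) and the signalling ligand Wnt11 (-1.91), of which a second probe gave -0.13. The Rxrg probe lies on chromosome 1 from 169569624 to 169569683. Among genes measured on 1 array only, the growth factor Gdnf was at least 5.40-fold and Cntnap3 at least 5.09-fold higher, and Apol7c at least 8.28-fold lower. Immediate early genes, which neurons switch on with activity, lay below the control in 15 of 15 members (median -0.44), with Ccn1 (-1.22) and Btg2 (-1.03) past the rule. Olfactory bulb markers had a median of 0.43 and choroid plexus markers -0.31, with 0 members of either list past the rule. In all, 100 genes were higher and 70 lower among 22691 measured, and 12 of 56 lists stood apart from random lists where the nominal 5% gives 2.8. In a simulation of the high-dose brain 6.9% of unchanged lists stood apart, above the nominal share. That simulation varied each gene separately. Real lists share members and their genes can vary together, so more lists than the nominal number can stand apart without an effect of dose. The same holds for the nominal numbers given below. With normexp background correction and quantile normalization the count of genes was 68. This normexp setting adds an offset of 50 to each spot, which shrinks differences of dim genes by construction.

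In the brain at the high dose, genes of the choroid plexus, the tissue that makes cerebrospinal fluid, were lower and genes of sperm formation higher than in the control. All 11 choroid plexus markers lay below the control and 8 passed the rule, with a median of -1.62. Among them were the potassium channel subunit Kcne2 (-2.08, array error 0.22), Sostdc1 (4.01-fold lower), the water channel Aqp1 (-1.98) and the bicarbonate carrier Slc4a5 (-1.93), 2 transporters of the named families. The higher genes were led by the protamines Prm1 (5.54, array error 0.23) and Prm2 (3.60) and the transition protein Tnp1 (3.88), which package sperm DNA. Tuba3b (2.94), Tcp11 (2.18) and Tcp10b (1.84, second probe 0.72), all best known from testis, were higher as well. The Prm1 probe lies on chromosome 16 from 10796450 to 10796509, and its level was -3.12 in the control brain, -3.99 at the low dose and 2.42 at the high dose. The probe of Kcne2 lies on the same chromosome from 92298155 to 92298214.

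Striatum markers, higher at the low dose, lay below the control in 11 of 11 members at the high dose, with a median of -0.62 and 0 past the rule. Hippocampus markers had a median of -0.36 and myelin markers -0.24, also with 0 past the rule. Prl, measured on both arrays here, differed by -3.54, and Gh was at least 6.25-fold lower. The pituitary list median was -3.25, or -1.12 with dim members at their bound and -0.28 without a filter on dim probes, where it did not stand apart. Other lower genes were Syt10 (-2.01), the prolactin receptor Prlr (-1.94), Wnt11 (-1.94) and the Mediator subunit Med22 (-1.93); second probes gave -0.30, -0.22 and 0.38 for Syt10, Prlr and Wnt11. The DNA polymerase Dntt (2.40), Rbakdn (2.29) and the water channel Aqp8 (1.52) were higher too, of which Rbakdn (2.33) and Aqp8 were also higher in the high-dose kidney. The neuropeptide receptor Nmur2 was at least 46.7-fold and the sperm enzyme Ldhc at least 11.4-fold higher, and Tmem154 at least 6.23-fold lower. Immediate early genes had a median of -0.36, with Ccn1 past the rule (-1.23). The unfolded protein response list had a median of 0.13, with its largest member Sdf2l1 at 0.91. In all, 46 genes were higher and 58 lower of 22796, and 14 of 57 lists stood apart against a nominal 2.85. The count was 40 with normexp correction and quantile normalization and 14 with a stricter filter on dim probes, so most of these genes were dim.

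Set directly against each other, the high-dose brain had lower striatum (median -2.27, 11 of 11 past the rule) and choroid plexus markers (-1.58, 8 of 11) than the low-dose brain, and higher hippocampus markers (0.82, 2 of 8). The hippocampus median ranged from 0.40 to 0.83 over the alternative settings and stood apart in each. The largest differences among higher genes were Prm1 (6.41), Prm2 (3.69) and Tnp1 (3.29). Among lower genes they were Slc10a4 (-3.21), Ido1 (-2.97) and Rxrg (-2.94). Altogether 73 genes were higher and 171 lower of 23171, with 89 passing under normexp correction and quantile normalization. Of 56 lists, 18 stood apart against a nominal 2.8.

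In the kidney at the low dose, the genes higher by the most included the gasdermin Gsdmc3 (2.85, array error 0.25), Sprr1a of the cornified envelope (2.49), the uroplakin gene Upk3a of the urinary tract lining (2.47), and Slc39a4 (2.27). Adrenal markers were lower: the steroid hydroxylase gene Cyp11b1 by at least 14.4-fold, Cyp21a1 by a difference of -3.70 and Star, which moves cholesterol into mitochondria, by -2.79. Of the 12 adrenal markers 9 were detected in kidney, 2 passed the rule, and their median was -0.68, or -0.47 over those measured on both arrays. The neuroendocrine granule gene Chgb was at least 10.96-fold lower and the brown fat gene Cidea differed by -2.11. The Slc39a4 probe lies on chromosome 15 from 76442866 to 76442925.

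The largest value in the low-dose kidney was that of Sh3kbp1 (-11.74), but 2 other probes of this gene gave -0.23 to 0.12; its reported probe had a level of 8.64 on the control array. Second probes also gave smaller values for Cyp21a1 (-0.82), Zfp169 (-0.37 against -1.76) and Slco4a1 (-0.30 and -0.13 against 1.14). The choline carrier-like gene Slc44a5 was lower (-1.14). The transcription factors Isl1 and Pou2f3 were at least 38.0-fold and 7.60-fold higher. Heat shock genes had a median of 0.24 with 13 of 14 members above the control, led by Hspa1a and Cryab (0.48 each), and 0 past the rule. Among cell type lists, medullary osmolyte genes (median 0.27), blood markers (0.25), fibroblast and matrix genes (0.20) and macrophage markers (0.16) stood apart above the control. Adipocyte (-0.24) and neutrophil markers (-0.27) stood apart below it, as the adrenal markers did. Clock output genes had a median of 0.31, with Dbp at 0.73. Sterol synthesis genes lay below the control in 18 of 19 members (median -0.19). Acute phase genes, made mostly by the liver in inflammation, had a median of -0.30 (-0.18 over members measured on both arrays), with Orm1 lower (-1.02); with the mean of probes the median was -0.06 and did not stand apart. In all, 46 genes were higher and 59 lower of 20950, and 21 of 52 lists stood apart against a nominal 2.6. With median scaling 53 were higher and 46 lower, and with quantile normalization 52 and 48, so the larger side depends on the scaling. The count was 20 with normexp correction and quantile normalization and 8 with a stricter filter on dim probes.

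The kidney at the high dose had more genes past the rule than any other comparison with a control, with genes of detoxification, inflammation and tubular injury higher. Targets of NRF2, the transcription factor that answers oxidative and electrophile stress, lay above the control in 19 of 20 members and 9 passed the rule (median 0.69). Examples were Gsta2 (2.64), Gstm3 (1.72) and Cbr3 (1.63). Glutathione transferases, some of which are in both lists, had 8 of 24 members higher and a median of 0.81, with Gstm4 at 1.65. Kidney injury genes had a median of 0.57: Havcr1, whose protein is the urinary marker KIM-1, was higher by 1.78, Lcn2, a lipocalin shed by injured tubules, by 1.61 and the cell cycle inhibitor Cdkn1a by 1.13, and Krt20 was at least 6.36-fold higher. The p53 target Phlda3 was higher as well (1.36; list median 0.38).

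Several inflammatory and immune lists had medians above the control in the high-dose kidney, while T cell (0.02) and B cell markers (-0.03) did not stand apart. The monocyte chemokine Ccl2 (3.18, array error 0.21) and the neutrophil chemokine Cxcl1 (2.45) passed the rule among 8 cytokine and adhesion genes (median 0.58). MHC class II genes had a median of 0.69 with 7 of 7 above the control and H2-Ab1 past the rule (1.17, other probes 0.98 to 1.10), and the interferon list 0.26 with Cxcl10 at 2.31. Macrophage markers had a median of 0.51 and neutrophil markers -0.92 (-0.60 over members measured on both arrays, and -0.22 without a filter on dim probes, where the list did not stand apart), with 0 members of either past the rule; Adgre1, a macrophage surface receptor, stood at 0.83 and S100a8, a neutrophil protein, at -0.98. Acute phase genes had 5 members higher and 1 lower of 16 detected. The serum amyloid genes Saa2 and Saa3 were at least 30.0-fold and 20.3-fold higher and Saa4 was higher by 1.99. The list median was 1.24, or 0.80 with genes measured on 1 array at their bound and 0.74 without them. Over the alternative settings the acute phase median went down to 0.50 and stood apart in each. Genes that are abundant in liver were higher alongside: the antitrypsin genes Serpina1e (3.45), Serpina1a (3.28) and Serpina1c (3.22), which share much of their sequence. The liver genes used to check the labels had a median level of -0.44 in the control kidney and 0.74 on this array. Whether the acute phase genes were higher in kidney cells or only as part of this liver signal was not tested, and 1 array cannot tell these apart.

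**Figure D1:**
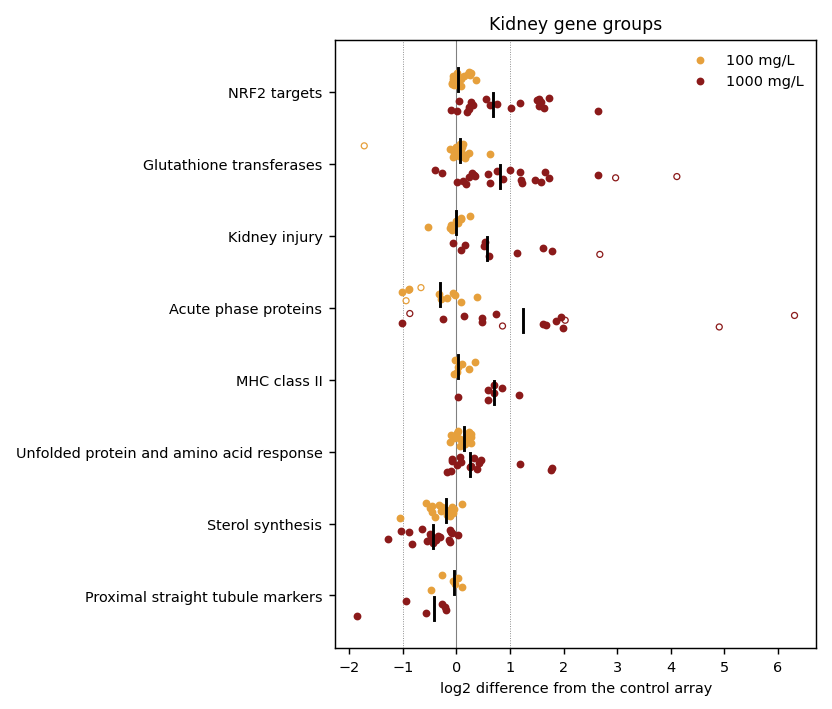
Log2 difference from the control kidney for each member of the kidney gene groups, at 100 mg/L (orange) and 1000 mg/L (dark red); filled points were measured on both arrays, open circles were well above background on 1 array only, black bars are list medians and dotted lines mark -1 and 1. NRF2 targets have a median of 0.69 and acute phase genes 1.24 at the high dose.

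Genes of the unfolded protein and amino acid response were higher in part (3 of 16, median 0.26), with Chac1 (1.79), Trib3 (1.76) and the asparagine synthetase gene Asns (1.20) past the rule. Sterol synthesis genes lay below the control in 18 of 19 members (median -0.44), and Cyp51 (-1.28) and Idi1 (-1.04) passed the rule. Markers of the straight proximal tubule lay below it in 6 of 6 members (median -0.42), with Slc22a7 past the rule and Napsa at -0.93, while proximal tubule markers had a median of 0.11, which did not stand apart with the mean of probes. Medullary osmolyte genes (median 0.52), thick ascending limb markers (0.24) and intercalated cell markers (0.22) stood apart above the control. Markers of the distal convoluted tubule, principal cells and podocytes did not stand apart. Proliferation genes had a median of 0.47 with 13 of 14 members above the control and 0 past the rule. Clock output genes had a median of 0.42, with Dbp higher by 1.47.

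Genes of sperm formation and of the adrenal gland also differed in the high-dose kidney. The germ cell genes Rbmy (5.36, array error 0.25), Ldhc (3.56) and Prm1 (3.42) were higher, and the spermatid gene Sly was lower (-1.94). Prm1 had a level of -0.09 in the control kidney, -1.46 at the low dose and 3.33 at the high dose. Adrenal markers were lower, as at the low dose, with a median of -1.09, or -0.86 with genes measured on 1 array at their bound and -0.61 without them: Cyp11b1 by at least 16.4-fold, Cyp21a1 by a difference of -3.41 (second probe -0.51), Star by -2.76 and the granule gene Chga by -2.69. Chgb was at least 12.5-fold lower. Both kidney doses use the same control array, and a high level of adrenal genes on that array alone would lower them at both doses. The 2 doses are therefore no repeat of each other for these genes. Adipocyte markers had a median of -0.60, with the brown fat gene Ucp1 lower (-1.42). Gadd45g, a growth arrest gene, was lower (-1.93), Gsdmc3 was higher (3.29), and the reported probe of Sh3kbp1 gave -11.69 against -0.42 to 0.13 for its other probes. Zfp169 gave -1.86 against 0.13 and 0.27 for its other probes. In all, 239 genes were higher and 117 lower of 21357, so 67.1% of the calls were higher. Of 52 lists, 34 stood apart against a nominal 2.6. With normexp correction and quantile normalization 151 genes passed, 83.4% of them higher.

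Against the low-dose kidney, the high-dose kidney had higher acute phase (median 1.18 with genes measured on 1 array at their bound), glutathione transferase (0.80, 8 of 24 past the rule), NRF2 (0.62, 9 of 20) and kidney injury genes (0.54, 3 of 10). Rbmy (5.20), Prm1 (4.79) and Tnp1 (4.66) differed most among higher genes and Slc22a26 (-2.32), Pou2f3 (-1.97) and the transcription factor Tal2 (-1.91) among lower ones. Adrenal markers did not stand apart between these exposed arrays, with a median of 0.03. There were 176 higher and 50 lower genes of 20897, 77.9% of them higher, against 109 genes and 91.7% with normexp correction and quantile normalization. Of 52 lists, 28 stood apart against a nominal 2.6.

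In the liver at the high dose, metallothioneins and genes of the circadian clock output were higher and genes of cholesterol synthesis lower. Mt1 and Mt2 had the largest differences among higher genes measured on both arrays, as given above. Clock output genes lay above the control in 10 of 10 members and 4 passed the rule: Usp2 (2.65, array error 0.22), the transcription factor Dbp (2.53), and the period genes Per3 (1.97) and Per1 (1.88). Their median was 1.42, or 1.28 with Ciart, measured on the exposed array only, at its bound and 0.96 without it. Clock genes of the opposite phase had a median of -0.58, with Arntl, which encodes the activator BMAL1, lower (-1.58). Noct, a rhythmic phosphatase gene, was higher (1.97). Sterol synthesis genes lay below the control in 18 of 19 members and 3 passed the rule (median -0.76): Sqle (-1.19), Hmgcs1 (-1.14) and Fdps (-1.07).

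The liver genes lower by the most included the cell cycle inhibitor Cdkn1a (-2.18, array error 0.30), the transcription factor Myc (-1.74), Depp1 (-1.72), Gadd45g (-1.70) and Junos, an RNA transcribed opposite Jun (-1.64). The p53 target list, which holds Cdkn1a, had a median of 0.15, above the upper limit of random lists. The NRF2 list did not stand apart, with its target Nqo1 higher (1.39) and Osgin1 lower (-1.09), and Asns was higher (1.39; unfolded protein and amino acid list median 0.15). Fasting and glucocorticoid genes had a median of -0.14, which did not stand apart with the mean of probes, with Igfbp1 (-1.41) and Pdk4 (-1.26) lower. Fatty acid synthesis genes had a median of -0.27, with 0 past the rule and the largest member Acly at -0.80. Acute phase genes had a median of -0.18 with 17 of 19 below the control, and the interferon list -0.20 with Ifit2 lower (-1.10). Other lower genes were Cldnd2 (-1.64), Wfikkn1 (-1.60) and Gngt1 (-1.59), all near background, and the lipid kinase Pip5k1a was higher by 2.11 on 1 probe and by 0.09 and 0.32 on the others. The muscle transcription factor Msc was at least 5.16-fold and Dnaaf4 at least 4.41-fold lower. Pancreas markers lay above the control in 7 of 7 detected members, with 1 past the rule (Cela2a, 1.66) and a median of 1.66, or 0.84 with genes measured on 1 array at their bound, and the list did not stand apart with the mean of probes; the trypsin gene Try5 was at least 8.01-fold higher. In all, 66 genes were higher and 88 lower of 19166, and 19 of 51 lists stood apart against a nominal 2.55. With normexp correction and quantile normalization 46 genes passed, and Myc, Junos, Cldnd2, Wfikkn1, Gngt1 and Slc41a3 did not.

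**Figure D2:**
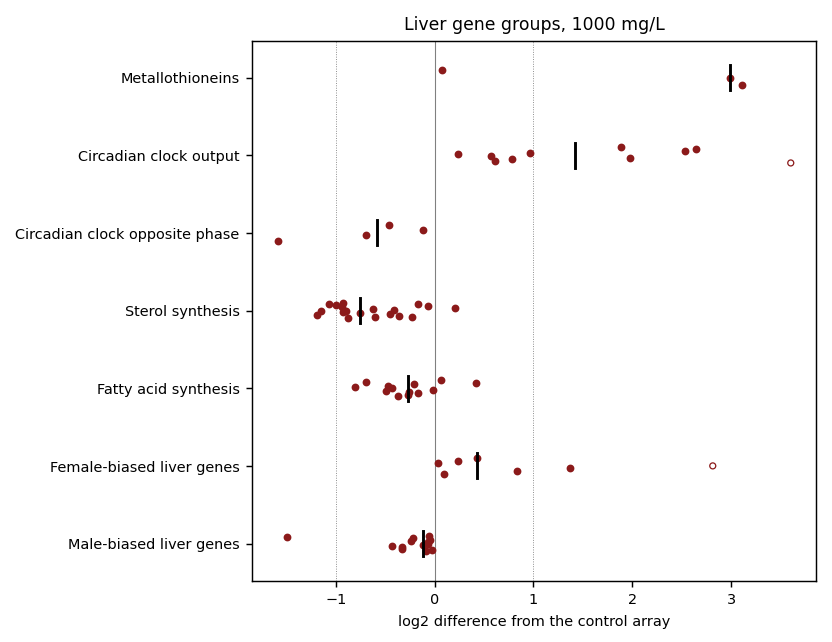
Log2 difference of the liver at 1000 mg/L (dark red) from the control liver for each member of the liver gene groups; filled points were measured on both arrays, open circles were well above background on 1 array only, black bars are list medians and dotted lines mark -1 and 1. Clock output genes have a median of 1.42 and sterol synthesis genes -0.76.

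The doses were compared within a tissue. In the kidney, the low- and high-dose differences correlated across 20746 genes at 0.562, and 12 genes were higher and 40 lower at both doses, while 2 were in opposite directions, Prm1 (-1.37 and 3.42) and Tnp1 (-1.57 and 3.09). In the brain the correlation was 0.429 across 22585 genes, with 2 genes higher and 23 lower at both doses. Both differences share 1 control array, and simulated unchanged groups against such a control, with a spread taken from the differences between high and low dose, gave correlations of 0.501 in kidney and 0.498 in brain. The covariance was 0.0436 against a simulated 0.0389 in kidney, and 0.0265 against 0.0354 in brain. Simulated overlaps held 92.7 and 75.5 genes on average, and independent lists would share 0.705 and 0.312. That spread holds any real effects too, so the simulated values are no measure of noise alone. The observed overlaps lay below the simulated averages in both tissues. The control is 1 array that cannot be split, and some or all of the excess over independent lists may come from it.

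Between tissues, the high-dose differences had correlations across genes, which are not independent replicates, of 0.0907 for brain and kidney, 0.0526 for kidney and liver and 0.0287 for brain and liver. Brain and kidney shared 16 higher and 2 lower genes where independent lists would share 0.446. Those higher included Prm1, Prm2 (2.39 in kidney), Tnp1, Tuba3b (1.92 in kidney) and Tcp11 (2.10 in kidney). Kidney and liver shared 7 higher and 4 lower genes where 0.730 would be shared, among them Mt1, Mt2, Dbp, Asns, Nqo1 and Gadd45g. Brain and liver shared 0.

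A limma fit over all 8 arrays, with tissue and dose as factors, asked which genes differed by dose in the same way across tissues. At an adjusted p of 0.05 it called 0 of 17448 genes for the high dose and 0 for the low dose, while 1180 and 421 genes had an unadjusted p under 0.05. A share of 0.05 of the tested genes, the nominal share without any effect, is more than the low-dose count and less than the high-dose count. The smallest limma adjusted p was 0.303, for the period gene Per2, with a difference of 0.66 (SE 0.07) that was above 0 in 3 of 3 tissues (0.57 in brain, 0.79 in kidney and 0.61 in liver). The next genes, none of which passed, were the carrier Slc23a3 (0.64), the receptor Tnfrsf12a (0.51), the endoplasmic reticulum genes Creld2 (0.58) and Herpud1 (0.45), and Ndrg1 (-0.46), with limma adjusted p of 0.617 to 0.685. Tissues may come from the same animals, which this fit cannot see.

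**Figure D3:**
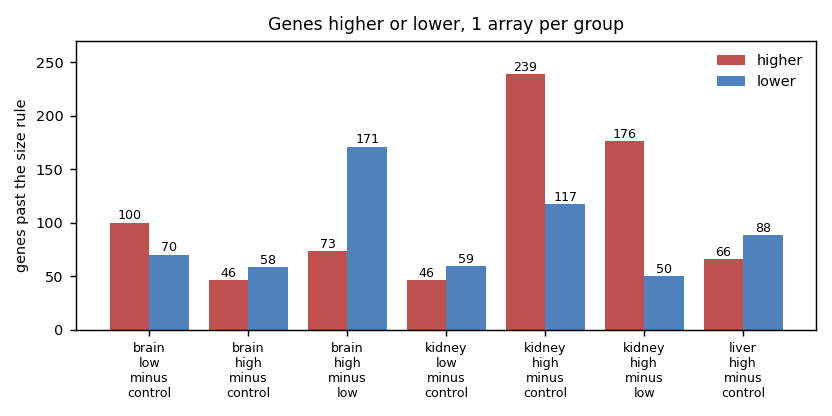
Number of genes higher (red) and lower (blue) past the size rule in each comparison of 1 array with 1 array. The high-dose kidney has 239 higher and 117 lower genes against its control, and the low-dose kidney 46 and 59.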

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

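Of the tests in this part, only the comparison of spermatid markers between brain and kidney was set out before its result was seen. All others, and the second marker lists, were chosen after the results were seen. In the spermatid comparison the correlation of 0.81 met the limit set beforehand for RNA from testis. The control levels of the same markers, which leave the question open, were not part of that limit. Each weighed pattern rests on 1 array per group.

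Spermatid transcripts were present on the high-dose brain and kidney arrays, with Prm1 at levels of 2.42 and 3.33 and Tnp1 at 0.27 and 1.49. In a list of 50 spermatid markers the median difference was 0.46 in brain and 1.21 in kidney (0.44 and 0.91 with genes measured on 1 array at their bound, 0.21 and 0.41 over the 23 and 24 measured on both arrays), 0.04 in liver, 0.01 in the low-dose brain and -0.16 in the low-dose kidney, and 24 markers were well above background on each control array of brain and kidney. A defect of single spots is argued against by 12 further markers well above background on the high-dose brain array than on the control. RNA from testis in both samples cannot be told apart from germ cell genes switched on by the high dose, since the brain median of 0.46 would follow from either: the gain in linear signal in brain and kidney had a Spearman correlation of 0.81 across 33 markers well above background on both high-dose arrays and 0.71 across all 50, but probe brightness, shared between tissues (0.77 for the control levels of the 50), would raise it under either. Spermatocyte markers (median 0.17 in brain and -0.10 in kidney, 20 in the list) and testis somatic markers (0.16 and -0.15, 11 in the list) stayed inside the range of random lists.

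Brain region markers differed between the exposed brain arrays, and those of the striatum did not follow the dose. The striatum list had a median of 1.56 at the low dose and -0.62 at the high dose, so the measured values did not grow with dose. A striatal effect that grows with dose is not excluded, since 1 piece with less striatum could hide it and no array repeats a group. Different shares of brain regions in the pieces taken may account for the region markers: a second list of 25 striatum genes had medians of 0.77 and -0.26, a second hippocampus list -0.26 and -0.04 and a second choroid plexus list -0.15 and -0.38. An effect on the choroid plexus that grows with dose cannot be told apart from a smaller share of that tissue, since its markers were lower at the high than at the low dose (-1.58) and no array repeats a group.

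Clock output genes were higher in the high-dose liver (median 1.42) and kidney (0.42). Animals of the control and high-dose groups killed at different times of day could give this: the differences of 14 clock genes in liver and kidney had a Spearman correlation of 0.78, against 0.10 for liver and brain and 0.41 for kidney and brain (16 genes). A second list of 20 clock-controlled genes had medians of 0.17 in liver, 0.03 in kidney and 0.15 in brain, of which the kidney's lay inside the range of random lists. An effect of lead on the clock cannot be told apart from a different hour of killing, which is not given in the sources used here. The low-dose kidney also had a median of 0.31. Both kidney doses use the same control array, which alone could raise both medians, so the low dose is no repeat of the high dose.

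The following results are listed because the same comparison, high dose against control, went in opposite directions in different tissues; none of the differences was tested. Between brain and kidney 2 genes past the rule were opposite, Cyp27b1 and 1 unnamed transcript, and between kidney and liver 5, namely Cdkn1a, Cela2a, Meg3 (other liver probes 0.91 to 1.38), Mfsd2a and 1 unnamed transcript; these names were chosen after the values were seen. The acute phase median was 1.42 higher in kidney than in liver, and the difference was not tested. The interferon list differed by 0.46 and macrophage markers by 0.67 between kidney and liver, also untested. Pancreas markers differed by -2.16 (kidney minus liver), untested; the kidney's median of -0.50 turned to 0.06 without a filter on dim probes, and the liver's 1.66 was 0.84 with bounds. Sterol synthesis genes differed by 0.51 between brain and kidney and by 0.83 between brain and liver, untested; the brain's own median of 0.07 turned to -0.01 with the mean of probes.

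For the high-dose effect across tissues, limma called 0 genes for the real grouping of the 6 control and high-dose arrays, and the highest other of the 10 splits called 68. With a real count of 0, each of the 10 splits calls at least as many by construction, and 10 splits are too few for a share under 0.05, so this decides nothing. The split with 68 genes sets both brain arrays and the control kidney against the rest. With tissue in the fit this structure of the samples leaves the high-dose kidney array alone to carry the difference (weight 1, control kidney -0.714), so the count has no replicate behind it.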

How the results depend on the processing

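Of these settings, only the count without marker genes was chosen after seeing the data; it gave 143, 85, 200, 101, 335, 214 and 149 genes for the 7 comparisons in the order brain low, brain high, brain high against low, kidney low, kidney high, kidney high against low and liver high. Against the counts of 170, 104, 244, 105, 356, 226 and 154, normexp correction with quantile normalization gave 68, 40, 89, 20, 151, 109 and 46. That normexp setting adds an offset of 50 to each spot, beside median processed signals of 42.0 to 115 per array. The offset shrinks log2 differences of dim genes by construction. Its share of the drop in counts was not tested. A stricter filter on dim probes gave 49, 14, 66, 8, 99, 72 and 46, and a limit of 3-fold gave 43, 42, 76, 21, 117, 83 and 26, both fewer by construction. Without a filter the counts after brain low, which stayed within 1.5 times, were 193, 382, 213, 545, 395 and 244, and a limit of 1.5-fold gave 375, 220, 481, 215, 728, 438 and 399. Other scalings, quantile normalization alone, the deposited value table, the mean of probes and no requirement on the array error kept every count within 1.5 times, and no gene called in both a main and an alternative setting changed direction. The correlation of the doses in brain was 0.624 and that of brain and kidney 0.219 under the stricter filter; the cause was not tested. Leaving out a tissue, limma called 0 to 2 genes for the high dose. Without brain, where 1 residual degree of freedom is left, Gadd45g (limma adjusted p 0.00288) and Cish (limma adjusted p 0.0442) were lower. Without kidney the low dose is 1 brain array, so only effect sizes are given for it. There Rxrg differed by 2.32 and the striatum marker Ppp1r1b by 1.51, on the array where striatum markers were higher. Settings that kept all tissues called 0. The smallest adjusted p for the high dose ranged from 0.00288 to 0.906 over the limma settings. Dose as a number and leaving out the low-dose arrays give no low-dose effect. Of 94 named values, 13 fell short of the rule under normexp and 4 with the mean of probes. Of 100 list calls against control, 16 ended on the same side of 0 with the mean of probes, 17 without matching, 8 without a filter, 6 with normexp and 4 with quantile normalization. A further 8 medians changed sign, and none of them stood apart. With the mean of probes these were pituitary markers in the low-dose brain (0.14), sterol synthesis in the high-dose brain (-0.0125), AHR targets in the low-dose kidney (-0.00125) and SLC transporters in the liver (-0.00138). Without a filter they were neutrophil markers in the low-dose kidney (0.00236), pancreas markers in the high-dose kidney (0.0638), and SLC transporters (-0.0428) and blood markers (-0.0225) in the liver. Signal over background limits the dim genes most. No paired analysis was possible because each group has 1 array and all replicate numbers are 1.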

Other observations

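Neutrophil markers had medians below the control on every exposed array. The list median was -0.33 in the low-dose brain, -0.50 in the high-dose brain, -0.27 and -0.92 in the low- and high-dose kidney and -0.42 in the liver (-0.26 with genes measured on 1 array at their bound), all below percentile 2.5 of random lists, with 0 members past the size rule; without a filter on dim probes the median stood apart in the high-dose brain alone. These 5 comparisons use 3 control arrays, and how often unchanged groups would agree this way was not computed. The calcium-binding protein S100a9 differed by -0.50, -0.92 and -0.78 in the high-dose brain, kidney and liver, and in the limma fit by -0.73 with an adjusted p of 0.688, which did not pass. Female-biased liver genes had a median of 0.43 in the high-dose liver with 7 of 7 detected members above the control. Cyp2a4 was higher (1.37) and Cyp2b13 at least 7.03-fold higher. The median of this list ranged from 0.23 to 0.44 over the alternative settings and stood apart in each. Male-biased liver genes had a median of -0.12 with 13 of 13 members below the control, which did not stand apart with quantile normalization, and the fatty acid elongase Elovl3 lower (-1.50).

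Some genes were higher in both exposed kidneys. Chosen after their values were seen, 4 of them were the uroplakin gene Upk3a (2.47 at the low and 2.29 at the high dose), the cornified envelope gene Sprr1a (2.49 and 2.90), and the keratins Krt19 (1.11 and 1.16) and Krt5 (1.04 and 1.03). Both differences use the same control array, which alone can raise genes at both doses. In kidney and liver at the high dose Cdkn1a differed by 1.13 and -2.18, and Cyp27b1, which activates vitamin D, differed by -1.14 in brain and 1.14 in kidney.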
